A study of Homo sapiens with 12 samples.

How the data were processed

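The series holds bulk RNA sequencing of cells that the sample titles and library names give as THP-1, an established human monocytic acute myeloid leukaemia line. The tag for the cell line counts upward from sample to sample instead, and all 12 libraries were taken as THP-1. Per the labels, cells received Cas9 with or without a guide RNA against IRAK4 and were grown from single cells, and clones were screened by PCR and Sanger sequencing. Wild-type and IRAK4 knockout cells were then treated with 50 nM CC-885 or with DMSO for 12 h. CC-885 is a small molecule that binds cereblon, the substrate receptor of a ubiquitin ligase, and directs the translation termination factor GSPT1 to it for degradation. The 12 libraries form 4 groups of 3. The labels do not say how many clones stand behind each genotype, nor whether replicates are separate cultures, so the knockout cannot be separated from clonal differences and each p-value measures only the spread between these libraries.

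The deposited table holds raw counts per gene symbol, with no normalization, for all 12 libraries. Per the labels, RNA was selected by polyA and libraries were made with a TruSeq kit and sequenced as paired-end reads. The authors' processing notes list the human build GRCh38, FastQC 0.11.2, HISAT2 2.0.5 and featureCounts 1.5.2, while the extraction protocol names FastQC 0.11.7 and the mouse build mm10 with HISAT2 2.0.5. The symbols in the table are human. The strand setting, the treatment of reads with several matches, and whether read pairs or single mates were counted are not given in the sources used here. Genes with near-identical copies and genes that overlap on opposite strands therefore carry an uncertainty that the errors below do not include.

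The table lists 30017 symbols, of which 7380 had no count in any library. Totals ranged from 46903984 to 56675539 counts per library, and the floor of 3 counts set against a group without counts covers counting error only. Standard deviations and standard errors include the spread between libraries. Genes were kept by edgeR's filterByExpr by group, which left 16010 symbols (53.3%) holding 99.98% of the counts. Library sizes were scaled by TMM factors. That scaling centres changes on the bulk of genes, and no measure of total RNA per cell was used here. Rises and falls are therefore relative and do not give amounts per cell. A quasi-likelihood model (edgeR 4.0.16, robust, R 4.3.3) was fitted to all 12 libraries with 1 coefficient per group and no covariate, and 5 contrasts were tested: CC-885 against DMSO in each genotype, knockout against wild type under each treatment, and the interaction, which is the response in knockout minus the response in wild type. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The biological coefficient of variation was 0.0899. Standard errors of log2 fold changes were derived from the F statistic. Levels are edgeR CPM values with TMM scaling, as mean ± SD of 3 libraries. The summed markers of other cell types and their member NKG7 are instead CPM of the library totals, without TMM factors.

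Gene lists were written from general knowledge before the data were examined. Of 31 lists with 779 members, 762 members were in the table and 708 were tested. The 29 lists with enough measured members were tested with camera (limma 3.58.1, correlation preset at 0.01), with camera at an estimated correlation and with fry, and p-values were adjusted over the lists of a comparison. Fry's p asks whether a list's genes move one way on balance and does not compare them with other genes. The lists cover the integrated stress response, cytosolic aminoacyl-tRNA synthetases, the ER unfolded protein response, nonsense-mediated decay factors, snoRNA host transcripts cleared by that decay, translation termination with the cereblon ligase, MYC target genes, MYC partners and stability regulators, Toll-like and interleukin-1 receptor signalling, NF-kB targets, the type I interferon response, immediate early genes, mitosis, DNA replication, p53 targets, apoptosis regulators, monocyte and macrophage differentiation, the HOXA and stem-like programme, granulocyte progenitor granule genes, cholesterol synthesis, heat shock chaperones, NRF2 targets, glycolysis and hypoxia, ribosomal proteins, oxidative phosphorylation and the proteasome. Markers of T and NK cells, B cells, and epithelial, stromal and endothelial cells were also listed. The erythroid list had 2 tested members and the list of mitochondrially encoded transcripts had 0 in the table, so neither was tested as a list.

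Genes named in the text follow a rule written before the data were examined. IRAK4, GSPT1, CRBN and MYC are given in every comparison. Each comparison adds the 6 largest rises and the 6 largest falls among called genes whose mean reaches 5 CPM in the higher group and whose groups do not overlap, a condition not applied to the interaction. Uncharacterised names were passed over. For each list described, up to 4 members with the smallest adjusted p are added. Members named because they stood against their list, and the genes of the closing section's histone and aryl hydrocarbon receptor groups, were chosen after their values were seen.

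Positions come from GENCODE release 29 on GRCh38, which placed 13948 of the tested symbols. After the data were seen, knockout effects were also examined along the chromosomes: the running median over 15 neighbouring expressed protein-coding genes (mean of at least 5 CPM) had to lie at least 0.4 log2 units from the median of all genes. This had to hold in the same direction under DMSO and under CC-885, over runs of at least 15 such genes. The order of genes was shuffled 100 times for comparison. Alternatives to each choice covered median-ratio, upper-quartile and library-size scaling, a Wald test (DESeq2 1.42.0), no count filter and a filter of 1 CPM in 3 libraries, and only the groups compared. They also covered replicate blocks, the library-name prefix (51 in 8 libraries, 52 in 4, meaning not given in the sources used here) as a covariate, the 51 libraries alone, and leaving out each library. All 3 knockout CC-885 libraries carry 51, while wild-type CC-885 replicate 3, which stands apart from its group, carries 52. Among wild-type DMSO libraries only replicate 1 carries 51, so values of that group in the 51 libraries alone rest on it. An alternative without the genes in the lowered chromosome stretches was added after the data were seen.

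The procedure was tested on simulated data with known changes. In each contrast 67, 67 and 66 genes were changed by 1.5-, 2- and 4-fold, and a list of 30 was raised. In the real data 34.7% to 78.9% of genes were called, which makes the adjusted threshold laxer. The recovered shares therefore do not give the detection rate in these data, and false calls with so many genes changing were not tested. Of genes changed 2-fold, 92.5%, 94.0%, 95.5%, 94.0% and 89.6% were recovered in the 5 contrasts in the order above, with 11 to 24 false calls in simulations of 15698 to 15739 genes. All 5 raised lists and 0 of 5 unchanged lists were called, and the chromosome search found 60 of 60 lowered genes and 0 others. Simulated genes were drawn independently of each other, so false calls of lists or stretches from genes that vary together were not tested. Shares of counts and summed markers were compared by two-sided exact permutation tests, whose smallest p for 3 against 3 is 0.1.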

Results

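PolyA RNA was measured in cells titled THP-1, a human monocytic acute myeloid leukaemia line, in a 2 by 2 design of genotype (wild type or IRAK4 knockout) and treatment (DMSO or 50 nM CC-885 for 12 h), with 3 libraries in each of the 4 groups. Totals were 46903984, 48796045 and 54905015 counts in wild type under DMSO and 52313937, 52287799 and 52564201 in wild type under CC-885. In knockout they were 47388925, 55123047 and 48086128 under DMSO and 56675539, 49048612 and 49002893 under CC-885. Between 18709 and 19219 symbols had a count in each library. Levels are mean CPM ± SD (n = 3 libraries a group), and changes are log2 fold changes ± SE from edgeR with adjusted p over 16010 genes. Counts of list members are over all genes, and the count adjusted over the list alone was equal unless it is printed as well. List p-values are from camera. List members named because they moved against their list or did not pass the test were chosen after their values were seen.

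IRAK4, the edited kinase of Toll-like and interleukin-1 receptor signalling (chromosome 12, 43758944 to 43789543, GRCh38), stood at 52.2 ± 1.57 CPM in wild type and 8.26 ± 0.847 CPM in knockout under DMSO, or 15.8% of wild type. Under CC-885 it stood at 72.8 ± 9.53 CPM in wild type and 30.7 ± 1.05 CPM in knockout, or 42.2% of wild type. The knockout libraries read 7.28, 8.72 and 8.78 CPM under DMSO and 31.7, 30.8 and 29.6 CPM under CC-885. GSPT1, the translation termination factor that CC-885 directs to degradation (chromosome 16, 11868128 to 11916082), measured 223 ± 8.58 and 253 ± 6.01 CPM in wild type under DMSO and CC-885 and 180 ± 9.65 and 298 ± 2.29 CPM in knockout. CRBN, the cereblon gene (chromosome 3, 3144628 to 3179727), measured 15.9 ± 0.475 and 38.1 ± 15.8 CPM in wild type and 17.7 ± 1.51 and 36.9 ± 1.07 CPM in knockout. MYC, a transcription factor of growth and ribosome synthesis (chromosome 8, 127735434 to 127741434), measured 273 ± 5.25 and 81.6 ± 7.34 CPM in wild type and 314 ± 8.47 and 49.3 ± 2.29 CPM in knockout. These are transcript levels, and protein was not analysed here.

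**Figure D1:**
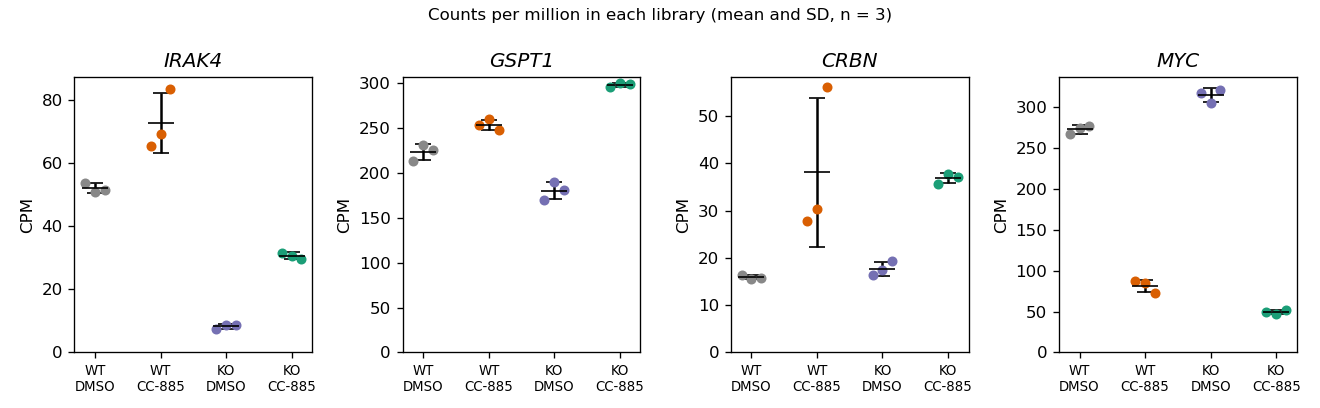
CPM (y axis, TMM-scaled) of IRAK4, GSPT1, CRBN and MYC in each of the 12 libraries, with points for libraries and a bar with error for the mean and SD of 3. IRAK4 in knockout averages 8.26 CPM under DMSO and 30.7 CPM under CC-885, and wild-type CC-885 replicate 3 stands at 56.2 CPM for CRBN against 27.7 and 30.3 CPM in the other replicates.

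The first principal component of log2 CPM held 64.6% of the variance and parted the treatments, and the next held 24.7% and parted the genotypes. Wild-type CC-885 replicate 3 differed from the other 2 replicates of its group by a chi-square per degree of freedom of 81.2 and 66.4, against 5.31 between those 2. Summed markers of other cell types reached at most 21.2 ± 1.67 CPM, for T and NK cell markers in knockout under DMSO, of which NKG7 gave 19.1 CPM. The T and NK cell sums were 12.0 ± 2.11 CPM in wild type under DMSO, 7.80 ± 0.828 CPM in wild type under CC-885 and 9.07 ± 0.476 CPM in knockout under CC-885. In the same group order, with knockout under DMSO before knockout under CC-885, the sums were 8.53, 7.97, 4.26 and 3.67 CPM for B cell markers, 10.6, 5.48, 11.9 and 5.30 CPM for erythroid markers, and 3.45, 2.58, 5.94 and 2.12 CPM for epithelial, stromal and endothelial markers.

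**Figure D2:**
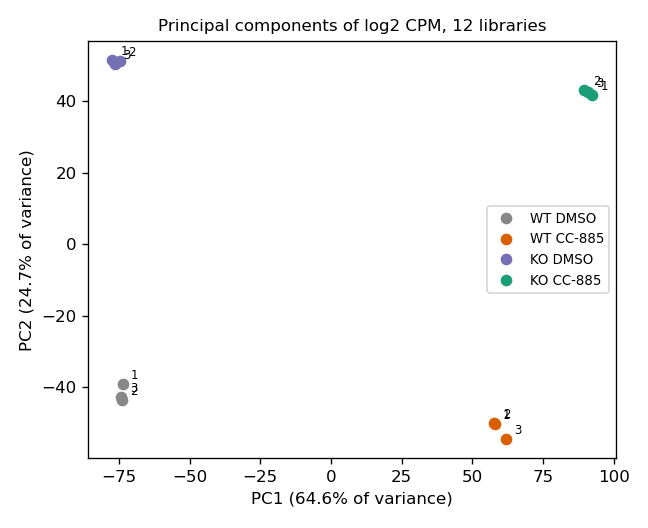
First and second principal components of log2 CPM (axes, with percent of variance), with 1 point per library, coloured by group and numbered by replicate. The first component (64.6%) separates CC-885 from DMSO and the second (24.7%) separates knockout from wild type.

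In wild-type cells, CC-885 was compared with DMSO to ask what a drug that directs GSPT1 to degradation does to transcripts. Among the largest rises were the transcription factor CREB5, by 10.05 ± 0.22, the drug efflux pump ABCB1 by 8.67 ± 0.18, the phosphatase DUSP8 by 8.63 ± 0.12 (0.887 to 354 CPM), the stress-induced factor ATF3 by 8.43 ± 0.09 (1.90 to 657 CPM), the neutrophil chemokine IL8 by 7.93 ± 0.64 and the AP-1 subunit JUN by 7.31 ± 0.12 (20.4 to 3231 CPM). Among the largest falls were the lipid droplet gene CIDEB at -3.66 ± 0.12, FAM111B at -3.23 ± 0.17, the receptor KIT at -3.11 ± 0.25, the Polycomb gene CBX2 at -3.05 ± 0.12, B3GNT7 at -2.99 ± 0.13 and the cohesion factor DSCC1 at -2.96 ± 0.15. MYC fell by 1.74 ± 0.07 (adjusted p = 1.5e-12), CRBN rose by 1.26 ± 0.22 (0.00036), IRAK4 by 0.48 ± 0.09 (0.000136) and GSPT1 by 0.18 ± 0.05 (0.00636).

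In all, 5710 genes were higher and 5865 lower, of which 2660 and 2033 changed at least 2-fold. The near-even split depends on the scaling, and upper-quartile factors gave 5364 higher and 6380 lower. The GSPT1 call was lost with library size alone (0.13, adjusted p = 0.0627) and with upper-quartile factors (0.11, adjusted p = 0.0764). IL8 read 426 CPM in CC-885 replicate 3 against 131 and 137 CPM in the others, and its change was 7.15 without that replicate. CREB5 reached 11.01 in the 51-prefix libraries alone, where wild-type DMSO replicate 1 is the only library of its group.

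Of 32 integrated stress response genes, 31 rose and 1, VLDLR (-0.43), fell, with a median of 2.70 (adjusted p = 1.5e-48). Among them were ATF3, the phosphatase subunit PPP1R15A (4.81 ± 0.07), the pseudokinase TRIB3 (3.93 ± 0.07) and the sestrin SESN2 (4.81 ± 0.08). All 22 immediate early genes rose (median 3.18, adjusted p = 8.0e-40), including EGR1 (7.05 ± 0.11), KLF6 (3.71 ± 0.07) and CSRNP1 (3.42 ± 0.08). Of 31 NF-kB and inflammatory targets, 24 rose and 1, TNFAIP2 (-0.33), fell, or 25 and 1 adjusted over the list alone (median 2.15, adjusted p = 6.2e-13). The prostaglandin synthase PTGS2 rose by 6.01 ± 0.09, the cytokine IL1B by 7.23 ± 0.14, the chemokine CCL3 by 5.96 ± 0.12 and the activation marker CD83 by 4.31 ± 0.11. Of 28 type I interferon response genes, 24 rose and 1, BST2 (-0.53), fell (median 1.33, adjusted p = 1.4e-05). IRF9 stood at 2.5 ± 0.10, IRF7 at 3.26 ± 0.12, IFIT2 at 3.39 ± 0.14 and STAT2 at 1.85 ± 0.09. The interferon call was lost (adjusted p = 0.458 with an estimated correlation), while those of the other 3 lists held (adjusted p = 9.6e-05, 0.00137 and 0.0146 with an estimated correlation).

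Nonsense-mediated decay clears transcripts with early stop codons and depends on translation termination. Of its 10 listed factors, 8 rose and 0 fell (median 0.59, adjusted p = 0.0229). SMG5 stood at 1.05 ± 0.05, SMG9 at 0.89 ± 0.06, UPF1 at 0.75 ± 0.05 and UPF3B at 1.01 ± 0.08. SMG6 (0.10) and SMG8 (-0.12) did not pass the test. Of 14 snoRNA host transcripts cleared by that decay, 11 rose and 3 fell (SNHG3 -0.86, SNHG6 -0.39, SNHG16 -1.11), with a median of 1.10 (adjusted p = 0.0102). SNHG12 rose by 2.51 ± 0.11, EPB41L4A-AS1 by 1.47 ± 0.07, SNHG17 by 1.39 ± 0.08 and SNHG15 by 1.05 ± 0.07. Both calls were lost (adjusted p = 0.308 and 0.458 with an estimated correlation).

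Of 32 DNA replication genes, 31 fell and ORC6 (-0.10) did not pass the test (median -1.55, adjusted p = 2.4e-26). The helicase subunit MCM2 stood at -2.02 ± 0.05, the methylation maintenance factor UHRF1 at -2.80 ± 0.07, the flap endonuclease FEN1 at -2.58 ± 0.08 and thymidylate synthase TYMS at -1.69 ± 0.05. All 12 granule genes of granulocyte progenitors fell (median -1.67, adjusted p = 0.000162), among them the serine proteases CTSG (-1.62 ± 0.07), PRTN3 (-2.00 ± 0.09) and ELANE (-1.73 ± 0.08) and the ribonuclease RNASE3 (-2.37 ± 0.16). Both calls held (adjusted p = 0.00435 and 0.0158 with an estimated correlation). Of 50 MYC target genes, 35 fell and 5 rose (ODC1, DDX21, WDR74, RRP12 and SUPV3L1), with a median of -0.59 (adjusted p = 1.6e-05, but adjusted p = 0.458 with an estimated correlation). UNG stood at -2.63 ± 0.06, TMEM97 at -2.17 ± 0.08, RRS1 at -1.49 ± 0.07 and the folate carrier SLC19A1 at -1.65 ± 0.08. Among 26 genes of Toll-like and interleukin-1 receptor signalling, 14 rose and 10 fell, and the list did not pass the test (median 0.81, adjusted p = 0.0710). Its adaptor TRAF6 rose by 1.78 ± 0.06, IRAK2 by 2.63 ± 0.10, PELI1 by 2.29 ± 0.09 and TLR6 by 2.03 ± 0.09.

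In IRAK4 knockout cells, CC-885 was compared with DMSO to ask how the edited cells respond. DUSP8 rose by 10.86 ± 0.13, CREB5 by 9.40 ± 0.24, JUN by 8.43 ± 0.13, ATF3 by 8.38 ± 0.09, IL1B by 8.18 ± 0.13 and the nuclear receptor NR4A3 by 7.90 ± 0.29. The largest falls were FAM111B at -5.26 ± 0.21, the ligand WNT7B at -4.96 ± 0.38, DSCC1 at -4.90 ± 0.18, UHRF1 at -4.76 ± 0.08, KIT at -4.75 ± 0.20 and HPDL at -4.64 ± 0.25. IRAK4 rose by 1.89 ± 0.10 (adjusted p = 2.4e-11), GSPT1 by 0.72 ± 0.05 (3.4e-09) and CRBN by 1.06 ± 0.22 (0.00102), and MYC fell by 2.67 ± 0.07 (9.1e-15).

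In knockout, 6229 genes were higher and 6398 lower, of which 3436 and 3227 changed at least 2-fold. In both genotypes 5108 genes were higher and 5122 lower, against 2222 and 2344 if the calls were independent, and 193 were called in opposite directions. Across genes, which are not independent replicates, log2 fold changes of the genotypes had a Pearson r of 0.894 and a slope of knockout on wild type of 1.09. Upper-quartile factors moved the median of all genes by -0.148 and gave 5576 genes higher and 7158 lower. NR4A3 stood at 9.18 without DMSO replicate 2.

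Of 32 integrated stress response genes, 28 rose and 3 fell (PSAT1 -0.27, PSPH -0.24, VLDLR -1.40), with a median of 2.07 (adjusted p = 3.4e-16). PPP1R15A rose by 5.64 ± 0.07, SESN2 by 3.78 ± 0.08 and the factor DDIT3 by 4.56 ± 0.10. All 22 immediate early genes rose (median 3.77, adjusted p = 1.1e-29). EGR1 stood at 6.62 ± 0.11, KLF6 at 3.75 ± 0.07 and CSRNP1 at 4.18 ± 0.09. Of 31 NF-kB targets, 25 rose and 1, TNFAIP2 (-0.44), fell, or 25 and 2 adjusted over the list alone (median 2.02, adjusted p = 1.2e-10). PTGS2 stood at 6.09 ± 0.10, CCL3 at 6.52 ± 0.12 and RELB at 3.44 ± 0.09. These 3 calls held (adjusted p = 0.00321, 0.00321 and 0.0133 with an estimated correlation). Of 28 interferon genes, 7 rose and 11 fell, and the list did not pass the test (median -0.15, mean 0.04, adjusted p = 0.895, and median 0.01 with the prefix as a covariate). IRF7 rose by 3.61 ± 0.13 and IRF9 by 1.28 ± 0.10, while BST2 (-1.36 ± 0.07) and CMPK2 (-1.70 ± 0.11) fell.

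Of 10 decay factors, 9 rose and SMG8 (0.12) did not pass the test (median 1.06, adjusted p = 0.00158). SMG5 stood at 1.76 ± 0.05, UPF1 at 1.32 ± 0.05, SMG9 at 1.30 ± 0.06 and UPF3B at 1.29 ± 0.08. Of 14 snoRNA host transcripts, 11 rose and 3 fell (SNHG3 -0.96, SNHG6 -0.56, SNHG16 -1.69), with a median of 1.25 (adjusted p = 0.00529). SNHG17 stood at 2.38 ± 0.08, SNHG12 at 3.42 ± 0.12, SNHG15 at 1.94 ± 0.07 and EPB41L4A-AS1 at 1.97 ± 0.08. Both calls were lost (adjusted p = 0.199 and 0.441 with an estimated correlation). Of 32 DNA replication genes, 31 fell and ORC6 (-0.10) did not pass the test (median -2.24, adjusted p = 8.0e-32). MCM2 stood at -3.60 ± 0.05, MCM3 at -2.93 ± 0.06 and the reductase subunit RRM2 at -4.01 ± 0.08. All 12 granule genes fell (median -2.11, adjusted p = 2.3e-05). CTSG stood at -2.20 ± 0.07, ELANE at -2.29 ± 0.08, PRTN3 at -2.51 ± 0.09 and RNASE3 at -3.11 ± 0.13. Both calls held (adjusted p = 0.00321 and 0.00911 with an estimated correlation). Of 50 MYC target genes, 33 fell and 10 rose (median -0.59, adjusted p = 0.00067, but adjusted p = 0.538 with an estimated correlation). UNG stood at -3.24 ± 0.07, SLC19A1 at -2.63 ± 0.09, TMEM97 at -2.31 ± 0.08 and RRS1 at -1.71 ± 0.07. Of 26 receptor signalling genes, 13 rose and 9 fell without a call for the list (median 0.43, adjusted p = 0.122), and TRAF6 stood at 2.21 ± 0.06, PELI1 at 3.07 ± 0.09, TAB2 at 1.75 ± 0.05 and IRAK2 at 2.98 ± 0.09.

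**Figure D3:**
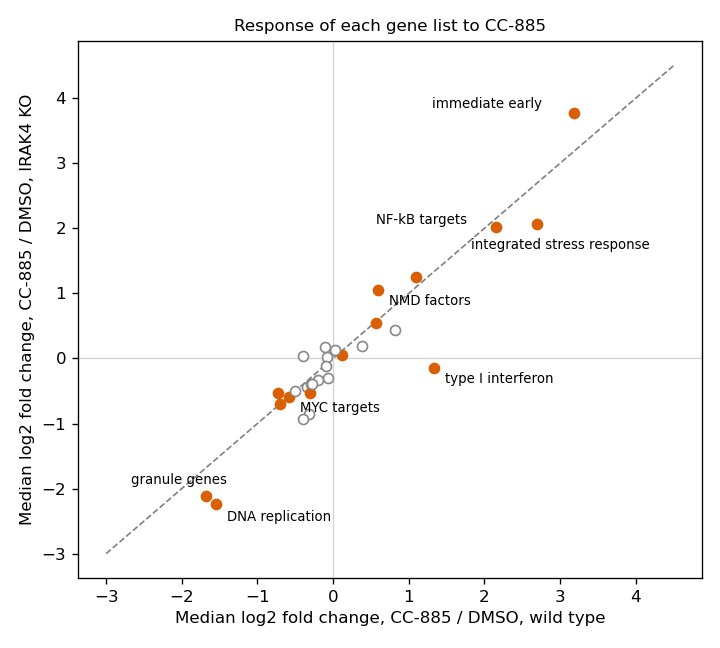
Median log2 fold change of each of the 29 tested gene lists under CC-885 against DMSO in wild type (x axis) and in knockout (y axis), with filled points for lists called in either genotype and a dashed line of equal response. Integrated stress response genes lie at 2.70 and 2.07, type I interferon genes at 1.33 and -0.15, and DNA replication genes at -1.55 and -2.24.

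Knockout and wild type were compared under DMSO to ask what differs before treatment. IRAK4 was lower in knockout at -2.66 ± 0.10 (adjusted p = 1.7e-11). The cyclic GMP phosphodiesterase PDE9A had 0 counts in wild type and 903 over the 3 knockout libraries, at least 301-fold higher against a floor of 3 counts over the group. The transcription factor BHLHE22 (6.33 ± 0.18), the keratin KRT17 (6.33 ± 0.32), WIPF3 (5.43 ± 0.19), IGSF9 (5.08 ± 0.15) and TMEM176B (4.87 ± 0.24) were also higher. The largest falls were CXorf57 at -7.61 ± 0.23, the ketosteroid reductase AKR1C1 at -7.49 ± 0.50 (770 against 4 counts over 3 libraries), the microtubule-severing gene FIGN at -7.15 ± 0.30, the homeobox gene ALX1 at -6.96 ± 0.27, the collagen COL4A5 at -6.74 ± 0.36 and PAWR at -6.73 ± 0.32.

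GSPT1 was lower at -0.31 ± 0.05 (adjusted p = 0.000219), MYC higher at 0.20 ± 0.06 (0.0143), and CRBN did not pass the test (0.16 ± 0.22, 0.593). In all, 3415 genes were higher and 4543 lower, of which 1131 and 1069 changed at least 2-fold. Upper-quartile factors moved the median of all genes by 0.123 and gave 4685 higher and 3036 lower, or 60.7% higher against 42.9%. MYC was not called with a block by library-name number (0.21, adjusted p = 0.0717), and CRBN was called with only the groups compared (0.21, adjusted p = 0.0380). Near their floor in knockout, ALX1 stood at -8.06 without knockout DMSO replicate 1, CXorf57 at -8.46, FIGN at -7.78 and COL4A5 at -6.12 without replicate 2, and COL4A5 at -8.08 without replicate 3. In the 51-prefix libraries alone, where wild-type DMSO replicate 1 is the only library of its group, BHLHE22 stood at 6.97, TMEM176B at 4.19 and COL4A5 at -8.10.

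Granule and monocyte genes were higher in knockout under DMSO. Of 12 granule genes, 11 rose and CAMP (0.69) did not pass the test, or 12 rose adjusted over the list alone (median 1.62, adjusted p = 4.9e-15). CTSG stood at 1.58 ± 0.07, AZU1 at 2.03 ± 0.10, RNASE3 at 2.17 ± 0.12 and PRTN3 at 1.19 ± 0.08. Of 26 monocyte and macrophage genes, 14 rose and 3 fell (CD86 -0.90, CD36 -0.35, LGALS3 -0.36), with a median of 0.76 (adjusted p = 3.2e-08). The peptidase ANPEP stood at 2.55 ± 0.09, the cathepsin CTSD at 1.16 ± 0.06, CD68 at 0.95 ± 0.06 and the calcium-binding S100A8 at 3.76 ± 0.18. Both calls held (adjusted p = 0.000693 and 0.00375 with an estimated correlation).

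Of 28 interferon genes, 24 were lower and 3 higher (MX2 0.82, STAT2 0.42, HERC5 0.34), with a median of -1.93 (adjusted p = 1.2e-10). The antiviral genes TRIM22 (-3.08 ± 0.16), OAS1 (-2.33 ± 0.14) and OAS2 (-2.15 ± 0.13) and the factor IRF7 (-1.93 ± 0.12) were among the lower. Of 50 MYC target genes, 38 were lower and 0 higher, or 41 and 0 adjusted over the list alone (median -0.40, adjusted p = 1.1e-07). RRP12 stood at -1.23 ± 0.06, NOLC1 at -1.22 ± 0.07, SUPV3L1 at -1.02 ± 0.07 and AIMP2 at -0.87 ± 0.06. Of 14 snoRNA host transcripts, 13 were lower and ZFAS1 (-0.27) did not pass the test (median -0.67, adjusted p = 0.000183). SNHG12 stood at -1.48 ± 0.12, EPB41L4A-AS1 at -0.87 ± 0.08, SNHG7 at -0.55 ± 0.06 and SNHG3 at -1.50 ± 0.16. These 3 calls were lost (adjusted p = 0.297 with an estimated correlation for each). Of 10 decay factors, 6 were lower, and the list did not pass the test (median -0.19, adjusted p = 0.0626), although it did without wild-type DMSO replicate 2 (-0.22, adjusted p = 0.0436) and without knockout DMSO replicate 2 (-0.21, adjusted p = 0.0352). UPF2 stood at -1.19 ± 0.07, SMG5 at -0.36 ± 0.05, SMG6 at -0.36 ± 0.09 and UPF1 at -0.22 ± 0.05, and UPF1 was not called with upper-quartile factors (-0.09, adjusted p = 0.187). The integrated stress response list was not called (7 higher, 14 lower, or 7 and 15 adjusted over the list alone, median -0.10, adjusted p = 0.154). DDIT4 stood at -1.99 ± 0.09, ASNS at -1.13 ± 0.08, XPOT at -0.62 ± 0.06 and SLC3A2 at -0.57 ± 0.07. Neither were NF-kB targets (8 higher, 9 lower, median -0.06, adjusted p = 0.588), where TNF stood at -2.95 ± 0.19, ICAM1 at -1.54 ± 0.16, RELB at -0.81 ± 0.08 and NFKB2 at -1.01 ± 0.11. Of 26 receptor signalling genes, 7 were higher and 5 lower (MYD88 -0.19, IRAK3 -0.46, TRAF6 -0.19, PELI1 -0.48, TICAM1 -0.24), without a call for the list (median 0.11, adjusted p = 0.0738), and TLR4 stood at 1.02 ± 0.08, IL1R1 at 1.45 ± 0.13, IRAK2 at 1.14 ± 0.11 and TLR1 at 0.98 ± 0.12.

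Genes lower in knockout lay together on 3 chromosomes, in 4 stretches found after the data were seen. They span 0.197 to 52.8 Mb of chromosome 5 (69 genes, median -1.21 under DMSO and -1.13 under CC-885), 0.134 to 133 Mb of chromosome 10 (349 genes, -1.02 and -0.92), 19.4 to 47.7 Mb of chromosome 12 (54 genes, -1.42 and -1.45) and 65.2 to 109 Mb of chromosome 12 (103 genes, -0.98 and -0.86). Of these 575 genes, 95.5% were lower in knockout under both treatments, a share favoured by a search that asked for lower running medians under both. IRAK4 lies in the chromosome 12 stretch from 19.4 Mb, and among other named genes ALX1, PAWR, AKR1C1, DDIT4, UPF2, DDX21, RRP12, NOLC1, SUPV3L1, NFKB2, IRAK3, PFKP, PGAM1, KLF6, IFIT2, HSP90B1, MDM2, HMGCS1 and IDI1 lie in these stretches too. Counting all 806 tested symbols of any type in them (5.03% of those tested), they hold 680 of the 4543 genes lower under DMSO (15%). A fit without them, in which the TMM factors were computed again, gave 3057 genes higher and 4488 lower under DMSO and 4061 and 4476 under CC-885. The new factors moved the median of all genes by -0.0427 and -0.0319, so these counts reflect the scaling as well as the genes left out. This alternative was added after the data were seen.

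**Figure D4:**
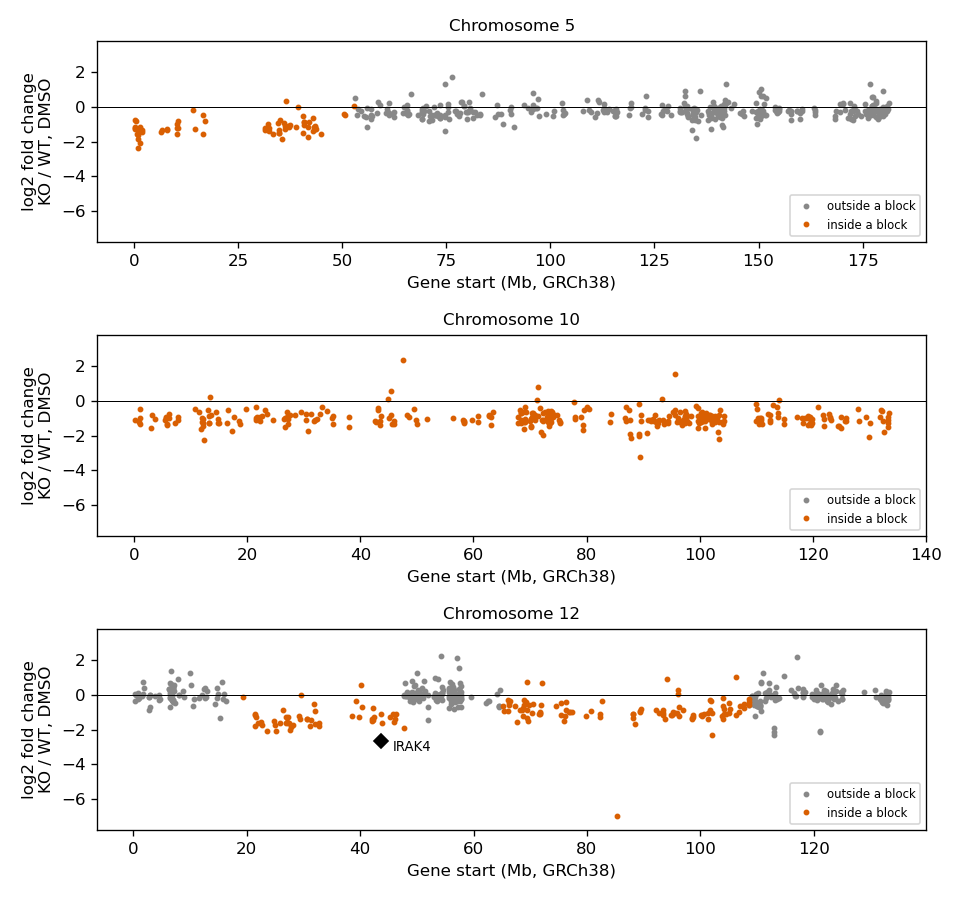
Log2 fold change of knockout over wild type under DMSO (y axis) for expressed protein-coding genes along chromosomes 5, 10 and 12 (x axis, gene start in Mb), with genes inside the 4 lower stretches in orange. The stretches have medians of -1.21 (chromosome 5), -1.02 (chromosome 10), and -1.42 and -0.98 (chromosome 12), and IRAK4 (black diamond) lies at -2.66.

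Knockout and wild type were compared under CC-885 to ask what differs after treatment. IRAK4 was lower in knockout at -1.25 ± 0.09 (adjusted p = 1.1e-08) and MYC at -0.73 ± 0.07 (1.3e-07), and GSPT1 was higher at 0.23 ± 0.05 (0.00162). BHLHE22 was higher by 7.57 ± 0.19, the xenobiotic-metabolising enzymes CYP1A1 by 5.43 ± 0.51 and CYP1B1 by 5.35 ± 0.23 (20.6 ± 0.637 against 838 ± 284 CPM), the IgA receptor FCAR by 4.66 ± 0.27, WIPF3 by 4.42 ± 0.19 and IGSF9 by 4.25 ± 0.17. The largest falls were ALX1 at -7.64 ± 0.28, CXorf57 at -6.97 ± 0.20, the interferon-induced genes IFI27 at -6.96 ± 0.75 and IFI44L at -5.90 ± 0.63, FIGN at -6.65 ± 0.28 and INPP5J at -6.10 ± 0.31.

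CRBN did not pass the test (-0.04 ± 0.21, adjusted p = 0.874), but it was called higher without wild-type CC-885 replicate 3 (0.35, adjusted p = 0.000629) and in the 51-prefix libraries alone (0.34, adjusted p = 0.000186). In all, 4453 genes were higher and 4931 lower, of which 933 and 1541 changed at least 2-fold. Left-out libraries moved IFI27 to -6.27 (wild-type CC-885 replicate 3), CYP1A1 to 4.75, FIGN to -7.28 and INPP5J to -6.78 (knockout CC-885 replicate 1), and ALX1 to -8.39 (knockout CC-885 replicate 3). IFI27 stood at -6.30 with the prefix as a covariate and -6.36 with a block by library-name number.

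All 28 interferon genes were lower in knockout under CC-885 (median -3.40, adjusted p = 5.5e-37). OAS1 stood at -4.14 ± 0.15, CMPK2 at -2.70 ± 0.11, IRF9 at -2.36 ± 0.10 and OAS2 at -4.31 ± 0.14. Of 32 integrated stress response genes, 28 were lower and 2 higher (ATF4 0.28, PPP1R15A 0.68), with a median of -1.22 (adjusted p = 6.0e-21). DDIT4 stood at -2.96 ± 0.08, asparagine synthetase ASNS at -1.65 ± 0.07, and the serine synthesis enzymes PSPH and PHGDH at -1.66 ± 0.07 and -1.23 ± 0.05. All 32 DNA replication genes were lower (median -0.78, adjusted p = 3.8e-19). MCM3 stood at -1.72 ± 0.05, MCM2 at -1.50 ± 0.05, UHRF1 at -2.19 ± 0.08 and CDT1 at -1.35 ± 0.06. Of 12 granule genes, 9 were higher and MPO (-0.04), MS4A3 (0.13) and RNASE2 (0.02) did not pass the test (median 0.90, adjusted p = 6.9e-05). AZU1 stood at 1.86 ± 0.10, CTSG at 1.0 ± 0.07, CEBPE at 1.98 ± 0.17 and RNASE3 at 1.43 ± 0.17. Of 26 monocyte and macrophage genes, 13 were higher and 6 lower (median 0.46, adjusted p = 0.00315). ANPEP stood at 2.01 ± 0.09, CTSD at 1.10 ± 0.06, CD68 at 0.91 ± 0.06 and APOE at 2.89 ± 0.19. These 5 calls held (adjusted p = 0.0435, 0.00428, 0.0184, 0.0184 and 0.0435 with an estimated correlation).

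Of 24 glycolysis and hypoxia genes, 13 were lower and 5 higher (SLC2A3 0.66, HK2 0.98, PDK1 0.73, BNIP3L 0.35, KDM3A 0.57), with a median of -0.39 (adjusted p = 0.00483, and adjusted p = 0.0435 with an estimated correlation). PFKP (-1.95 ± 0.05) and PGAM1 (-1.93 ± 0.06) lie in the lowered stretches, LDHA stood at -1.22 ± 0.06 and PGK1 at -0.68 ± 0.05, and the call was lost without the genes of those stretches (median -0.14, adjusted p = 0.331). Of 50 MYC target genes, 33 were lower and 2 higher (WDR74 0.27, GRWD1 0.30), or 35 and 2 adjusted over the list alone (median -0.46, adjusted p = 1.5e-06, but adjusted p = 0.375 with an estimated correlation). RRP12 stood at -1.28 ± 0.06, NOLC1 at -1.23 ± 0.07, UNG at -1.0 ± 0.06 and SLC19A1 at -1.30 ± 0.08. Decay factors were not called (6 higher, with UPF2 -0.74 and SMG6 -0.22 lower, median 0.24, adjusted p = 0.358), and SMG5 stood at 0.36 ± 0.05 and UPF1 at 0.36 ± 0.05. The snoRNA hosts were not called (2 higher and 8 lower, or 2 and 10 adjusted over the list alone, median -0.49, adjusted p = 0.104), with SNHG15 (0.56 ± 0.07) and SNHG17 (0.39) higher and SNHG16 (-1.24 ± 0.08), SNHG3 (-1.59 ± 0.17) and SNHG6 (-0.69 ± 0.10) lower. That list was called without wild-type CC-885 replicate 2 (-0.58, adjusted p = 0.0464) and without the genes of the stretches (-0.53, adjusted p = 0.0388). Receptor signalling genes were at the threshold (15 higher, 7 lower, median 0.27, adjusted p = 0.05002) and were called under several alternatives, with adjusted p = 0.0369 the smallest, without knockout CC-885 replicate 3. IRAK2 stood at 1.5 ± 0.09, IL1R1 at 1.75 ± 0.13, TLR4 at 0.99 ± 0.08 and the adaptor MYD88 at -0.98 ± 0.06. NF-kB targets were not called (11 higher, 9 lower, median 0.09, adjusted p = 0.322). IL1B stood at 1.49 ± 0.09, CCL3 at 1.19 ± 0.08, NFKB1 at 0.62 ± 0.06 and CCL4 at 1.51 ± 0.15.

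The interaction asks whether the response to CC-885 differs between genotypes. The rise of IRAK4 was larger in knockout by 1.41 ± 0.13 (adjusted p = 1.9e-06) and that of GSPT1 by 0.54 ± 0.08 (7.6e-05), the fall of MYC was larger at -0.93 ± 0.09 (3.2e-06), and CRBN did not pass the test (-0.20 ± 0.31, 0.660). Responses were higher in knockout for CYP1A1 (4.37 ± 1.41), the cytokine LIF (4.08 ± 0.33), the matrix gene THBS1 (3.12 ± 0.35), DUSP8 (2.22 ± 0.21), ZNF462 (2.22 ± 0.38) and the lysine-degrading enzyme AASS (2.21 ± 0.32). They were lower for INHBE (-3.58 ± 0.24), STC2 (-3.43 ± 0.45), the interferon-induced GTPase MX2 (-3.35 ± 0.24), the glutathione-degrading enzyme CHAC1 (-3.19 ± 0.22), RAB33A (-2.70 ± 0.19) and SAMD9 (-2.53 ± 0.41).

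In all, 2871 genes had a higher and 2691 a lower interaction, of which 258 and 705 differed at least 2-fold. With a filter of 1 CPM in 3 libraries the 258 became 170, while the 705 stayed within 1.5 times its value. Of the 5562, 3600 moved the same way in both genotypes and further in knockout, 422 the same way and less in knockout, 193 in opposite directions, 903 were called in knockout alone, 422 in wild type alone and 22 in neither. The share higher was 51.6%, against 39.7% with upper-quartile factors (2168 and 3291) and 38.5% with no count filter (1993 and 3185). CYP1A1 was below 1 CPM in 3 of the 4 groups (0.0671, 0.138 and 0.141 CPM) and 6.01 ± 3.91 CPM in knockout under CC-885. Its call was lost in 8 of the 12 leave-one-out fits, 3 of them those without a wild-type CC-885 replicate (4.17, 4.36 and 4.61), 3 without a wild-type DMSO replicate (3.92, 4.61 and 4.51) and 2 without knockout DMSO replicate 2 or 3 (4.18 and 4.47). It was lost too with no count filter (4.29, adjusted p = 0.0768) and with the prefix as a covariate (4.37, adjusted p = 0.0729). Without knockout CC-885 replicate 1 its value was 3.69. In the 51-prefix libraries alone, wild-type DMSO replicate 1 is the only library of its group. There CYP1A1 stood at 5.39 and was not called, STC2 stood at -5.58, SAMD9 at -1.89 and CRBN at 0.31. Without wild-type CC-885 replicate 3 CRBN stood at 0.19.

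Of 32 integrated stress response genes, 25 had a lower and 2 (ATF4 0.34, PPP1R15A 0.83) a higher response in knockout, or 26 and 3 adjusted over the list alone (median -0.85, adjusted p = 1.9e-21). TRIB3 stood at -1.59 ± 0.08, PSPH at -1.76 ± 0.10 and PSAT1 at -1.57 ± 0.11. Of 32 DNA replication genes, 26 had a lower and 0 a higher response (median -0.68, adjusted p = 1.8e-25). MCM2 stood at -1.58 ± 0.07, UHRF1 at -1.96 ± 0.10, MCM3 at -1.43 ± 0.07 and RRM2 at -1.71 ± 0.11. Both calls held (adjusted p = 0.00369 and 0.00825 with an estimated correlation). Of 28 interferon genes, 23 had a lower and 0 a higher response, or 24 and 0 adjusted over the list alone (median -1.70, adjusted p = 1.3e-23). CMPK2 stood at -2.27 ± 0.15, XAF1 at -1.76 ± 0.16 and OAS2 at -2.15 ± 0.19. Of 10 decay factors, 7 had a higher and 0 a lower response, or 8 and 0 adjusted over the list alone (median 0.42, adjusted p = 0.000456). SMG5 stood at 0.71 ± 0.07, UPF1 at 0.57 ± 0.07 and SMG9 at 0.41 ± 0.09. These last 2 calls were lost (adjusted p = 0.139 with an estimated correlation for each).

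Among 14 snoRNA hosts, SNHG15 (0.89 ± 0.10), SNHG17 (0.99 ± 0.11), SNHG12 (0.91 ± 0.16), SNHG7 (0.42 ± 0.08) and EPB41L4A-AS1 (0.50) had a higher and SNHG16 (-0.58) a lower response (median 0.19, adjusted p = 0.0396, but adjusted p = 0.629 with an estimated correlation). That call was lost without wild-type DMSO replicate 1 (0.13), wild-type CC-885 replicate 1 (0.07) or 2 (0.10), knockout DMSO replicate 3 (0.16) or knockout CC-885 replicate 3 (0.13). MYC target genes were not called (10 higher, 13 lower, median -0.01, adjusted p = 0.786), with medians of 0.03 without wild-type DMSO replicate 1 and 0.05 without wild-type CC-885 replicate 3. SLC19A1 stood at -0.98 ± 0.11, EXOSC5 at -0.97 ± 0.14, UNG at -0.60 ± 0.09 and ODC1 at 0.46 ± 0.07. Receptor signalling genes were not called (7 higher, 8 lower, or 8 and 8 adjusted over the list alone, median 0.02, mean -0.14, adjusted p = 0.761). MYD88 stood at -0.79 ± 0.08, TLR6 at -0.79 ± 0.13, TAB2 at 0.59 ± 0.07 and PELI1 at 0.78 ± 0.13. NF-kB targets were not called (10 higher and 4 lower, or 11 and 4 adjusted over the list alone, median 0.13, adjusted p = 0.144). RELB stood at 1.18 ± 0.11, NFKB1 at 0.68 ± 0.08 and TNF at 1.84 ± 0.24 higher and CXCL1 (-1.68), CXCL2 (-1.63), CXCL3 (-4.14) and SOD2 (-0.59 ± 0.09) lower. The mean of CXCL3 did not reach 5 CPM in any group, so its value is uncertain.

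Ribosomal proteins took 7.89 ± 0.594% of counts in wild type under DMSO and 6.16 ± 0.700% under CC-885, and 7.75 ± 0.295% and 4.85 ± 0.367% in knockout (exact permutation p = 0.1 for each treatment comparison, adjusted p = 0.133, the smallest 3 against 3 allows being 0.1). Of 76 ribosomal protein genes, 48 fell in wild type (47 adjusted over the list alone, median -0.31, adjusted p = 0.0149) and 63 in knockout (median -0.53, adjusted p = 0.000664). Of 20 cytosolic aminoacyl-tRNA synthetases, 13 rose and 4 fell in wild type (median 0.57, adjusted p = 1.6e-05) and 14 rose and 4 fell in knockout (0.55, 0.00305), the falls in both being FARSA, FARSB, HARS and QARS. Of 26 mitosis genes, 23 fell in wild type (24 adjusted over the list alone, median -0.70, adjusted p = 8.0e-05), and 20 fell while AURKA (0.20) and CDC20 (0.41) rose in knockout, or 20 and 3 adjusted over the list alone (-0.70, 0.00937). Of 24 cholesterol synthesis genes, 16 fell and HSD17B7 (1.28) and STARD4 (0.29) rose in wild type, or 17 and 2 adjusted over the list alone (-0.73, 0.00025), and 15 fell and 6 rose in knockout (-0.52, 0.0122). In wild type 9 of 21 p53 targets rose and 7 fell (median 0.12, adjusted p = 0.0226), and in knockout 10 rose and 8 fell without a call (0.05, 0.0569). In the order above, these calls were lost (adjusted p = 0.877, 0.678, 0.135, 0.340, 0.245, 0.441, 0.167, 0.377 and 0.135 with an estimated correlation). The p53 list was called in knockout when single libraries were left out, namely wild-type DMSO replicate 1 or 3, wild-type CC-885 replicate 3 or any knockout CC-885 replicate (smallest adjusted p = 0.0346). It was also called with a block by title number (0.0290) and with the prefix as a covariate (0.0153).

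The other lists were not called under CC-885 in either genotype, with medians in wild type and knockout of -0.20 and -0.33 for the ER unfolded protein response, -0.07 and 0.02 for translation termination and the cereblon ligase, -0.11 and 0.18 for MYC partners, 0.39 and 0.19 for apoptosis regulators, -0.35 and -0.44 for monocyte and macrophage genes, -0.09 and -0.12 for the HOXA programme, -0.51 and -0.50 for heat shock chaperones, -0.32 and -0.86 for NRF2 targets, -0.29 and -0.40 for glycolysis and hypoxia, -0.29 and -0.39 for oxidative phosphorylation and 0.03 and 0.12 for the proteasome. Median, mean and test differed in sign in wild type for MYC partners (mean 0.05), NRF2 targets (mean 0.21), glycolysis (mean 0.28) and the proteasome (mean -0.03), and in knockout for translation termination (mean -0.09) and glycolysis (mean 0.09). Oxidative phosphorylation (adjusted p = 0.0564 in wild type, 0.1 in knockout) was called in wild type with library size alone (0.0364) and without DMSO replicate 2 or 3 or CC-885 replicate 3 (0.0441, 0.0450 and 0.00543), and in knockout without wild-type CC-885 replicate 3 (0.0400).

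Between genotypes under DMSO, the ER unfolded protein response was higher in knockout (13 of 24 higher, HSP90B1 and DNAJC3 lower, median 0.28, adjusted p = 0.0026), as were cholesterol synthesis (15 of 24 higher, HMGCS1 and IDI1 lower, or 18 and 2 adjusted over the list alone, 0.33, 0.00386) and p53 targets (11 of 21 higher, MDM2, BAX and TNFRSF10B lower, 0.36, 0.0132). Lower were heat shock chaperones (13 of 16 lower, HSPA4L higher, or 13 and 2 adjusted over the list alone, -0.49, 0.00228), immediate early genes (12 of 22 lower, KLF10 and BTG2 higher, -0.32, 0.0132), NRF2 targets (11 of 17 lower, GCLC, OSGIN1 and TALDO1 higher, or 11 and 4 adjusted over the list alone, -0.40, 0.0262), oxidative phosphorylation (19 of 41 lower, NDUFA13 and NDUFB10 higher, or 20 and 2 adjusted over the list alone, -0.19, 0.0161), mitosis (14 of 26 lower, -0.27, 0.0262), the proteasome (20 of 31 lower, or 20 and 1 adjusted over the list alone, -0.25, 0.0262), synthetases (9 of 20 lower, CARS higher, -0.13, 0.0351) and glycolysis (12 of 24 lower and 6 higher, or 13 and 6 adjusted over the list alone, -0.16, 0.0384). These 11 calls were lost (adjusted p = 0.212 to 0.551 with an estimated correlation), and the glycolysis call also without the genes of the lowered stretches (median -0.06, adjusted p = 0.808). Calls near the threshold were also lost with library size alone (synthetases 0.0556, glycolysis 0.0541), without wild-type DMSO replicate 1 (mitosis 0.0653, glycolysis 0.0545, oxidative phosphorylation 0.0507, proteasome 0.0567), without knockout DMSO replicate 1 (mitosis 0.0531) and without knockout DMSO replicate 3 (synthetases 0.0631, glycolysis 0.0540). DNA replication (2 higher, RRM2 and TYMS, 15 lower, median -0.13, adjusted p = 0.147), ribosomal proteins (-0.05, but 0.02 without wild-type DMSO replicate 1), translation termination (0.03, mean 0.12, test lower), MYC partners (-0.12), apoptosis regulators (-0.11) and the HOXA programme (-0.09, with KIT at 3.38) were not called.

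Under CC-885, knockout was higher in cholesterol synthesis (16 of 24 higher, HMGCS1, IDI1 and EBP among the lower, median 0.43, adjusted p = 0.00185) and p53 targets (12 of 21 higher, TNFRSF10B, ZMAT3 and CCNG1 lower, 0.20, 0.00949). It was lower in NRF2 targets (12 of 17 lower, GCLC and SQSTM1 higher, -0.79, 4.5e-06), ribosomal proteins (41 of 76 lower, -0.33, 0.00185), heat shock chaperones (11 of 16 lower, HSPA4L higher, -0.54, 0.00352), synthetases (12 of 20 lower, DARS, FARSB and VARS higher, -0.27, 0.00564) and oxidative phosphorylation (22 of 41 lower, NDUFA9, NDUFS1, NDUFV2 and UQCRFS1 higher, -0.27, 0.00949). These 7 calls were lost (adjusted p = 0.0551 to 0.696 with an estimated correlation). Not called were the ER unfolded protein response (0.00), translation termination (-0.02, mean 0.05), MYC partners (0.03, mean -0.14), immediate early genes (-0.05), mitosis (-0.11), apoptosis regulators (-0.19), the HOXA programme (-0.37) and the proteasome (-0.01, but 0.05 without wild-type CC-885 replicate 3).

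In the interaction, the response was higher in knockout for immediate early genes (10 of 22 higher, EGR1 and IER2 lower, or 11 and 2 adjusted over the list alone, median 0.33, adjusted p = 0.00514) and the proteasome (11 of 31 higher, PSMB5 and PSMB7 lower, 0.18, 0.0291). It was lower for ribosomal proteins (18 of 76 lower, RPS26 higher, or 15 and 0 adjusted over the list alone, -0.27, 0.000337), NRF2 targets (9 of 17 lower, FTH1 and SQSTM1 higher, -0.61, 0.00112), the ER unfolded protein response (13 of 24 lower, DNAJC3 higher, or 14 and 2 adjusted over the list alone, -0.31, 0.00193), granule genes (6 of 12 lower, -0.54, 0.0220) and monocyte and macrophage genes (7 of 26 lower, -0.07, 0.0377). These 7 calls were lost (adjusted p = 0.139 to 0.750 with an estimated correlation). The proteasome call was also lost without wild-type DMSO replicate 1 (0.0539), wild-type CC-885 replicate 1 (0.0768) or 2 (0.0713) or knockout CC-885 replicate 3 (0.0704), and the monocyte call without wild-type DMSO replicate 2 (0.0541), without knockout DMSO replicate 1 (0.0708) and with a block by title number (0.0535). Not called were synthetases (-0.03), translation termination (-0.13, test higher), MYC partners (0.16), mitosis (0.08), p53 targets (-0.17, test higher), apoptosis regulators (0.00, mean -0.13), the HOXA programme (-0.15), cholesterol synthesis (0.07), heat shock chaperones (-0.07), glycolysis (-0.29) and oxidative phosphorylation (-0.15). Some of these medians depended on single libraries, with heat shock chaperones at 0.04 and oxidative phosphorylation at -0.03 without wild-type CC-885 replicate 3, and heat shock chaperones at 0.02 without knockout DMSO replicate 2. Lists of T and NK, B and epithelial, stromal and endothelial markers were not called in any of the 5 comparisons (smallest adjusted p = 0.133, for the last under DMSO), and the medians of B cell markers differed in sign from their means in wild type under CC-885 (-0.40 and 0.36) and between genotypes under DMSO (0.44 and -0.25), as did those of T and NK cell markers in wild type under CC-885 (-0.06 and 0.06). In knockout under CC-885 the test of B cell markers pointed lower with a median of 0.03.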

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

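Of the tests here, that on nonsense-mediated decay and the regrouping of libraries were chosen before the data were examined, and those on mixed cells, on the chromosome segment and on the stress response were chosen only after the result was seen. The results below were picked out because the interaction test found a different response to CC-885 in knockout and wild type (adjusted p under 0.05). Values are interaction log2 fold changes, positive where the response was higher in knockout.

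IRAK4 counts in knockout rose more under CC-885 than in wild type (interaction 1.41), from 15.8% to 42.2% of wild type. Wild-type cells mixed into the knockout CC-885 cultures are argued against by 4 genes nearly silent in knockout under DMSO (ALX1, IFI27, FIGN and CXorf57), which stood at a median of 0.774% and at most 0.939% of wild type under CC-885. That test rests on few genes, and its minimum was lowered from 10 to 3 genes after only these 4 qualified, without which it would decide nothing. A property of the segment is argued against as a source of the rise by all 53 expressed neighbours, whose interactions lay below that of IRAK4, with a median of 0.03. The deficit left under CC-885 (-1.25) is no larger than theirs (median -1.46, 34 of 53 below IRAK4), whereas under DMSO it was (-2.66 against -1.39, 0 below). An interaction of 1.41 is consistent with edited IRAK4 transcripts being cleared by nonsense-mediated decay under DMSO and spared when CC-885 hinders translation termination, a hypothesis that the factors (median 0.42) and snoRNA hosts (0.19) of that decay do not settle. A stronger induction of the edited gene itself, and differences between clones, stay open and were not tested.

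Integrated stress response genes rose less in knockout (median interaction -0.85, 25 of 32 lower), while ATF4 (0.34) and PPP1R15A (0.83) responded more. The wild-type library that stands apart does not account for this, since the median was -0.855 without it (adjusted p = 1.39e-20, and adjusted p = 0.00522 with an estimated correlation). A weaker exposure of the knockout cells is argued against by a slope of knockout on wild-type responses of 1.09 across genes and by DNA replication genes falling further in knockout (-0.68). Without the 2 members in the lowered chromosome stretches, the other 30 had a median of -0.746 (adjusted p = 2.04e-19). With 25 of 32 lower, 2 members could not have set the median, so that outcome was largely fixed in advance. A difference brought by the genotype remains a hypothesis, and clonal differences stay open as untested.

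Other lists that differed were the type I interferon response (-1.70), NRF2 targets (-0.61), granule genes (-0.54), the ER unfolded protein response (-0.31), ribosomal proteins (-0.27), monocyte and macrophage genes (-0.0653), immediate early genes (0.33) and the proteasome (0.18). Each of these 8 calls was lost (adjusted p = 0.139 to 0.750 with an estimated correlation), as were those of the decay factors (0.139) and snoRNA hosts (0.629).

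Among the stress response genes named in the report, interactions were -3.19 for CHAC1, -3.43 for STC2, -1.76 for PSPH, -1.59 for TRIB3, -1.57 for PSAT1, -1.03 for SESN2 and -0.97 for DDIT4. They were -0.97 for VLDLR, -0.78 for PHGDH, -0.52 for ASNS and -0.51 for DDIT3. Replication and proliferation genes gave -1.58 for MCM2, -1.43 for MCM3, -1.96 for UHRF1, -1.71 for RRM2 and -1.08 for FEN1. They were -0.99 for CDT1, -0.56 for TYMS, -1.94 for DSCC1, -2.03 for FAM111B, 0.44 for AURKA and 0.75 for CDC20. Interferon genes gave -3.35 for MX2, -2.27 for CMPK2, -2.15 for OAS2, -1.81 for OAS1 and -1.76 for XAF1. Others were -1.30 for IFIT2, -1.22 for IRF9, -1.07 for STAT2, -1.02 for HERC5, -0.83 for TRIM22, -0.83 for BST2 and -2.53 for SAMD9. Decay factors gave 0.71 for SMG5, 0.57 for UPF1, 0.45 for UPF2 and 0.41 for SMG9. The host transcripts gave 0.91 for SNHG12, 0.89 for SNHG15, 0.99 for SNHG17, 0.42 for SNHG7, 0.50 for EPB41L4A-AS1 and -0.58 for SNHG16.

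Inflammatory genes gave 1.84 for TNF, 1.20 for ICAM1, 1.18 for RELB, 0.68 for NFKB1, 0.94 for IL1B, 0.56 for CCL3 and 1.96 for CCL4. Lower responses were -1.68 for CXCL1, -1.63 for CXCL2, -4.14 for CXCL3 (mean below 5 CPM in every group) and -0.59 for SOD2. Receptor signalling genes gave -0.79 for MYD88, -0.79 for TLR6, -0.46 for TLR1, 0.59 for TAB2, 0.78 for PELI1, 0.43 for TRAF6 and 0.55 for TICAM1. Early-response genes gave 2.22 for DUSP8, 1.72 for NR4A3, 1.12 for JUN, 0.88 for KLF10, 0.76 for CSRNP1, -0.44 for EGR1 and -0.30 for IER2. MYC and its targets gave -0.93 for MYC, -0.98 for SLC19A1, -0.97 for EXOSC5 and -0.60 for UNG. Higher were 0.46 for ODC1, 0.50 for DDX21, 0.50 for WDR74, 0.61 for GRWD1 and 0.29 for SUPV3L1. Myeloid genes gave -0.58 for CTSG, -0.56 for ELANE, -0.51 for PRTN3, -0.74 for RNASE3 and -1.64 for RNASE2. Others were -1.06 for MPO, -0.54 for ANPEP and -1.63 for KIT. The listed T and NK cell marker NKG7 gave -0.80.

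Metabolic genes gave 1.76 for HK2, 0.69 for PDK1, 0.45 for KDM3A, -0.35 for BNIP3L, -0.38 for PFKP, -0.65 for PGAM1, -0.73 for LDHA and -0.40 for PGK1. Sterol genes gave 0.31 for HMGCS1, 0.40 for HSD17B7 and -0.44 for EBP. Redox genes gave -1.56 for OSGIN1, -0.31 for TALDO1, 0.34 for FTH1 and 0.74 for SQSTM1. Respiratory chain genes gave 0.39 for NDUFA9, 0.51 for NDUFS1, 0.39 for NDUFV2, 0.48 for UQCRFS1 and -0.53 for NDUFA13. Genes of protein synthesis gave 0.54 for GSPT1, 0.52 for VARS, -0.56 for CARS, -0.58 for QARS and 0.25 for RPS26. Folding and proteasome genes gave -0.40 for HSP90B1, 0.46 for DNAJC3, -0.38 for PSMB5 and -0.28 for PSMB7. The p53 targets gave 0.85 for MDM2, 0.48 for BAX and -0.83 for ZMAT3. The remaining genes gave 4.37 for CYP1A1, 2.14 for CYP1B1, 4.08 for LIF, 3.12 for THBS1, 2.22 for ZNF462, 2.21 for AASS and 1.24 for BHLHE22. Lower were -3.58 for INHBE, -2.70 for RAB33A, -2.28 for KRT17, -2.12 for WNT7B and -1.85 for HPDL. Smaller differences were -1.68 for TMEM176B, -1.26 for CBX2, -1.01 for WIPF3, -0.90 for B3GNT7, -0.83 for IGSF9 and -0.62 for CIDEB. The CYP1A1 call was lost in 8 of 12 leave-one-out fits, which left out each wild-type library and knockout DMSO replicates 2 and 3 in turn, with values from 3.92 to 4.61, and its value was 3.69 without knockout CC-885 replicate 1.

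Regroupings of the libraries were also fitted. For each 2-group comparison, the 10 splits of its 6 libraries are too few for a share under 0.05. The real split (1 of 10) called 11575 genes for CC-885 in wild type, 12627 for CC-885 in knockout, 7958 between genotypes under DMSO and 9384 under CC-885, and the highest other split called 0 in each case. For the interaction, 2 of 100 assignments drawn from 200 called at least the 5562 genes of the real one. The other of these 2 called 9783 and swaps the genotypes under 1 treatment only, so that it tests the genotype effect, a structure of the samples. The next highest called 4166. Assignments that mix the genotypes put the genotype effect into the spread within groups, which lowers their calls with or without an interaction. The share of assignments therefore cannot decide whether the interaction calls arose by chance.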

How the results depend on the processing

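All alternatives were chosen before the data were examined except the one without genes of the lowered chromosome stretches, added after the results were seen. Each of the 10 counts of higher or lower genes stayed within 1.5 times its value under every alternative run, and no gene called under both an alternative and the reported setting changed sign. Leaving out single libraries gave 5450 to 5810 higher and 5545 to 6032 lower genes for CC-885 in wild type, 6021 to 6489 and 6085 to 6714 in knockout, 2930 to 3900 and 3854 to 5360 between genotypes under DMSO, 3963 to 4739 and 4426 to 5106 under CC-885, and 2382 to 3627 and 2269 to 3245 for the interaction. The highest of each came without wild-type CC-885 replicate 3. Residuals of samples sharing a title number had a median correlation of 0.0153, with 2 of 18 pairs above 0.1. Within a library-name prefix 3 of 28 pairs were above 0.1, across prefixes 0 of 26 (lowest -0.267). Counts of at least 2-fold changes stayed within 1.5 times except 170 against 258 higher in the interaction with a filter of 1 CPM, and 678 against 1069 lower between genotypes under DMSO without the stretches, by construction.

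CRBN between genotypes under CC-885 (-0.04) reversed to 0.34 in the 51-prefix libraries and to 0.35 without wild-type CC-885 replicate 3, with -0.23 to 0.35 over left-out libraries, and that replicate had the highest CRBN. With an estimated correlation 5, 5, 2, 6 and 2 lists were called in the 5 comparisons, against 14, 12, 16, 14 and 12. With fry 22, 24, 26 and 23 were called in the first 4, where fry asks another question. Of genes changed 1.5-fold in simulated data at this depth, 73.1% to 88.1% were recovered in the 2-group comparisons and 49.3% in the interaction. The simulations changed far fewer genes than were called in the data, so these shares do not give the detection rate here. Small differences may have gone undetected, at a rate that was not measured.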

Other observations

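All tests in this part were chosen only after the result was seen. Histone genes rose under CC-885, although most histone transcripts lack the polyA tail on which these libraries were selected. Of 54 measured, 49 rose and 0 fell in wild type (median 3.33, adjusted p = 9.3e-11 over the 8 groups examined this way) and 52 rose and 0 fell in knockout (3.90, 6.4e-12), and both calls held (adjusted p = 0.0220 and 0.0345 with an estimated correlation). The linker histone HIST1H1C went from 2.11 ± 0.457 to 42.7 ± 5.32 CPM in wild type and from 4.86 ± 0.016 to 137 ± 6.84 CPM in knockout (n = 3), and HIST2H2BE from 1.13 ± 0.273 to 69.5 ± 23.4 and from 4.07 ± 0.581 to 119 ± 4.08 CPM. Between genotypes under CC-885 30 were higher and 1 lower (0.75, adjusted p = 6.1e-06, but adjusted p = 0.128 with an estimated correlation). In the interaction 10 were higher and 0 lower (0.79, adjusted p = 0.030, but adjusted p = 0.294 with an estimated correlation). HIST1H1C stood there at 0.47 (edgeR adjusted p = 0.0394) and HIST2H2BE, which did not pass the test, at -1.09 (0.0593). Histone genes have near-identical copies, so single members are uncertain.

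Genes tied to the aryl hydrocarbon receptor, a sensor of xenobiotics, were examined as a group of 8 after CYP1A1 and CYP1B1 were seen. A test with these 2 in it partly restates their change (adjusted p = 0.00105 in knockout and 0.00511 in wild type, but adjusted p = 0.0716 and 0.127 with an estimated correlation). Of the other 6, 4 rose and NQO1 (-1.12) fell in knockout (median 0.97, adjusted p = 0.00222, and adjusted p = 0.0300 with an estimated correlation). In wild type 4 of them rose and NQO1 (-0.36) and AHRR (-0.40, in a stretch lower in knockout) fell (0.996, adjusted p = 0.00331, and adjusted p = 0.0349 with an estimated correlation). TIPARP went from 22.9 ± 0.695 to 274 ± 11.4 CPM in wild type and from 21.4 ± 1.62 to 894 ± 120 CPM in knockout (interaction 1.80, adjusted p = 1.0e-07). AHR itself went from 9.41 ± 0.426 to 60.7 ± 4.06 CPM and from 15.2 ± 2.19 to 151 ± 4.21 CPM (interaction 0.62, adjusted p = 0.00115). NQO1 fell further in knockout (interaction -0.76, adjusted p = 0.00441). Over the 6 genes the interaction had a median of 0.44 (adjusted p = 0.0300, but adjusted p = 0.230 with an estimated correlation), and knockout against wild type under CC-885 was not called (0.16, adjusted p = 0.165). The other 6 groups were zinc finger genes (medians 0.60 in wild type and 0.70 in knockout under CC-885), tubulins (-0.59 and -0.80), HLA genes (-0.51 and -1.35), solute carriers (-0.24 and -0.28), interferon and chemokine genes (5.03 and 5.15) and mitochondrial ribosome genes (-0.34 and -0.30). HLA genes (camera adjusted p = 0.884 and 0.279) and solute carriers (0.0940 and 0.0879) were not called, nor were mitochondrial ribosome genes in knockout (0.0879). With an estimated correlation, only the interferon and chemokine calls held among these 6 groups (adjusted p = 0.0220 and 0.0345). That group's 6 measured genes include TNF, CCL3 and CCL4 of the NF-kB list. The type I interferon list was not called in knockout (median -0.15).

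Genes lower in knockout lie together in the 4 stretches of chromosomes 5, 10 and 12. Effects placed without regard to position are argued against, since the 575 genes in such stretches compare with at most 0 in 100 shuffled gene orders. In the median over these genes, the lowest wild-type and the highest knockout library differ by 0.845 (knockout -1.10 to -0.86, wild type -0.01 to 0.09). The genes were chosen from these same libraries, so a gap between genotypes was expected. A few libraries as its source are argued against, since every knockout library showed the drop. A library-name prefix is argued against by the 51 libraries, at -0.01 to 0.02 in wild type and -1.10 to -0.86 in knockout. The only knockout library with 52, DMSO replicate 3, stood at -0.99. The median interaction over these genes was 0.0619 and 95.5% were lower under both treatments. The search itself asked for running medians at least 0.4 lower under both treatments, so that share was largely set in advance. Drops of near-equal size were not required by it, but a drop under 1 treatment alone could not enter. Fewer copies of these segments in the knockout cells than in the wild-type cells remain a hypothesis, with no DNA measurement behind it. Loss in knockout and gain in wild type, and a change made by editing (IRAK4 lies in a chromosome 12 stretch) or one already present in the founding cell, stay open and were not tested.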
